A study of Mus musculus with 4 samples.

How the data were processed

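CTCF ChIP-seq was analysed in 4 libraries of the mouse B cell lymphoma line WEHI-231, 2 labelled control and 2 labelled stable TFII-I knockdown. Per the labels, clarified lysates of sonicated nuclei were precipitated with a commercial CTCF antibody and sequenced on an Illumina instrument. The submitters' processing notes name BWA, HOMER and the build mm9 without versions or roles. The names of the peaks in the deposited lists carry the word MACS, the name of a family of peak callers; the version, the parameters and any use of an input library are not given in the sources used here. One list was deposited per library, so peaks were read as called per sample and not on pooled libraries.

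Each deposited list gives a name, chromosome, start, end and a score per peak. The score is the authors' own value for a peak. Its lowest value of 50 and its discrete steps are those of the negative log10 of a Poisson p times 10, so that 50 was read as a p of 1e-05 and 100 as a p of 1e-10, and the highest value was 3100. The lists give no tag counts, fold enrichment or depth. The score was therefore used to describe, rank and filter peaks within a list. Because a score at a given enrichment grows with the number of tags, a library with fewer tags yields fewer and lower-scoring peaks from the same binding. Coordinates are printed as the lists give them, read as counted from 1. The last peak on chromosome 1 ends at 197135632, beyond the last gene of the gene table at hand, which is for the later build GRCm38 and was not used for positions.

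Replicates were compared by the share of peaks of one list that overlap a peak of another by at least 1 bp, with exact 95% Clopper-Pearson intervals. Peaks of all 4 lists that overlapped by at least 1 bp were merged into regions, and each region was classed by the libraries with a call in it. Where several peaks of a library fell in a region, the highest score was taken. Group values are means with the SD of 2 libraries, and 2 libraries against 2 allow no two-sided exact permutation p under 0.333. Shares between sets of regions were compared with Fisher's exact test and Benjamini-Hochberg adjustment over 21 chromosomes. Rank differences per chromosome were tested with 100000 random draws of as many regions. For comparison at the same control rank, the mean difference of autosomal regions in 20 bins of control rank was subtracted from each region. The strength of a control region was the mean of its ranks in both control lists.

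Before the data were examined, the tests, the alternatives and the rule for naming regions were fixed. The plan assumed tag densities, which the lists do not hold, and these were replaced by the mean rank by score within each list. The named regions are the 8 control-specific regions and the 4 knockdown-specific regions with the highest mean rank in the libraries that have them, and the 3 regions with the highest mean rank over all 4 libraries; the mitochondrial chromosome was left out of naming. The parts of the rule on changed tag density and on promoters of gene lists could not be applied. Of the planned analyses, 4 were not run at all: the test of tag density in shared regions, the share of promoter peaks per library, the promoter share of control-specific against shared regions, and the 16 gene lists at promoters. The latter 3 need an mm9 annotation, which was not used here. Peak strength per library was described by median scores, and its planned permutation test was also left out as scores of different lists are not on a common scale. The planned stricter threshold was taken as a score of 100, which is 2 times the lowest score.

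Alternatives for the overlap were a reciprocal overlap of 50%, peak centres within 500 bp, and merging of peaks within 500 bp. Further alternatives were the stricter score, lists limited to the length of the shortest (15309 peaks), lists without the mitochondrial and Y chromosomes, and leaving out each library in turn. Peak numbers were also compared within replicate numbers, with an exact sign-flip test. The background tag level of each library was estimated, after the lists had been seen, from the Poisson steps on which an excess of scores falls. Control peaks were then thinned to the background level of the knockdown lists by binomial sampling. The number of other regions called in both controls within 250 kb of a region on the autosomes was taken as local density. Windows of 3 Mb were compared with 1000 shuffles of the control-specific class among regions of the same strength.

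The calculations were made in python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots with matplotlib 3.10.9. The merging and overlap steps were tested on simulated data made from the 24467 peaks of control replicate 1. Of 533 peaks removed from both knockdown copies, 533 were recovered as control-specific regions, and all 23934 remaining peaks were found in the control list.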

Results

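CTCF is a zinc finger protein that binds insulators and gene promoters, and TFII-I is a transcription factor encoded by Gtf2i. CTCF binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in WEHI-231, a mouse B cell lymphoma line derived from a cross of BALB/c and NZB mice. The data comprised 4 CTCF libraries, 2 from control cells and 2 from cells with a stable knockdown of TFII-I. The title of the series poses the question whether TFII-I directs CTCF to gene promoters across the genome. Each library came as its own list of CTCF peaks with a position in the mouse build mm9 and the authors' score per peak, and sequencing depth was not given in the sources used here. The labels name 2 replicates per group without saying that they came from separate cultures, so the spread between them may be technical. The degree of TFII-I knockdown was not analysed here, and without an mm9 annotation the regions are given by position and not by gene.

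The control lists were longer than the knockdown lists. Control replicate 1 held 24467 CTCF peaks and control replicate 2 held 23873, a mean of 24170 ± 420 (SD, n = 2). Knockdown replicate 1 held 19076 peaks and knockdown replicate 2 held 15309, a mean of 17192.5 ± 2664 (SD, n = 2). The knockdown mean was 71.1% of the control mean, or 28.9% fewer peaks, and both knockdown lists were shorter than both control lists. Peaks in the knockdown lists were also narrower, with median widths of 328 and 446 bp against 483 and 507 bp in the controls. The peaks of a control library covered 12.2 Mb ± 0.195 (SD, n = 2) of the genome, 1.80 times the 6.76 Mb ± 0.425 (SD, n = 2) of a knockdown library. The two-sided exact permutation test of the peak numbers gave p = 0.333, the smallest value possible for 2 libraries against 2, so it could not pass 0.05.

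The scores of the peaks were lower in the knockdown lists as well. The median score was 111 and 107 in control replicates 1 and 2, and 85.5 and 79.1 in knockdown replicates 1 and 2. Peaks with a score of 100 or more, which stands for a p of 1e-10, made up 57.1% and 55.4% of the control peaks but 35.7% and 28.4% of the knockdown peaks. At the lower end, 17.0% and 18.8% of the knockdown peaks had a score under 60, against 10.7% and 11.2% of the control peaks. A score rises with sequencing depth as well as with enrichment, and so these values describe the lists and were not tested as a change in binding.

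Most knockdown peaks lay on a control peak, while many control peaks had no knockdown counterpart. Of the peaks of knockdown replicate 1, 90.2% overlapped a peak of control replicate 1 by at least 1 bp and 89.1% one of control replicate 2. For knockdown replicate 2 these shares were 91.4% and 91.0%. In the other direction, 70.0% and 70.8% of the peaks of control replicates 1 and 2 were found in knockdown replicate 1, and 57.2% and 58.4% in knockdown replicate 2. The control lists shared more with each other, with 85.2% of replicate 1 (95% Clopper-Pearson interval 84.8 to 85.7%) found in replicate 2 and 87.3% (86.9 to 87.7%) in reverse. Within the knockdown pair, 65.5% (64.9 to 66.2%) of replicate 1 was found in replicate 2 and 81.3% (80.7 to 82.0%) of replicate 2 in replicate 1. The share found depends on the length of the list searched. With the 15309 strongest peaks of each list, 80.5% of peaks were shared within the control pair and 71.7% within the knockdown pair. Then 74.2% of control peaks were found in a knockdown list and 74.4% of knockdown peaks in a control list. Lists of equal length make these 2 directions nearly equal by construction. The intervals cover counting error over peaks, which are not replicates.

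Merging the 4 lists gave 29116 CTCF regions, of which 11741 (40.3%) were called in every library. Both control libraries had a call in 20780 regions, and 3076 of these (14.8%, 95% Clopper-Pearson interval 14.3 to 15.3%) had no call in either knockdown library. These are named control-specific regions here. The reverse class, called in both knockdown libraries and in neither control, held 142 regions, which was 1.14% (0.963 to 1.35%) of the 12429 regions called in both knockdown libraries. Control-specific regions therefore outnumbered knockdown-specific regions 21.7 to 1. A further 5963 regions were called in both controls and in a single knockdown library, 4378 of them in replicate 1 and 1585 in replicate 2.

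The counts of pair-specific regions were largest when the libraries were paired by group. Control against knockdown gave 3218 regions called in both libraries of one pair and neither of the other. Pairing the libraries by replicate number gave 992 such regions, and the crossed pairing gave 831. With every list limited to its 15309 strongest peaks, the excess of the group pairing was smaller, at 1705 regions against 1189 and 1104. These are the only 3 ways to pair 4 libraries, so no test on the pairings could pass 0.05. At that length control-specific regions numbered 894 and knockdown-specific regions 811, but 733 of the 811 (90.4%) had a call in a complete control list, and 329 of the 894 (36.8%) had one in a complete knockdown list. List length bears on these shares too, since both complete control lists are longer than 15309 peaks and that of knockdown replicate 2 is not. Leaving out any of the 4 libraries, which loosens the definition, moved the control-specific count to between 4661 and 7454 and the knockdown-specific count to between 387 and 1103.

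**Figure D1:**
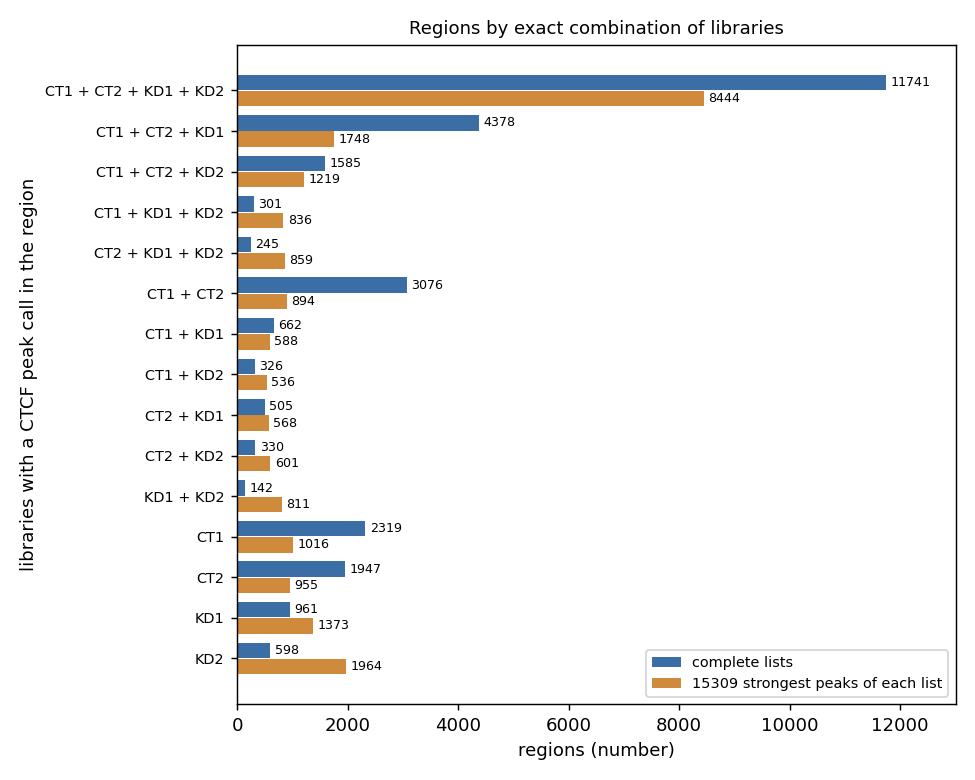
Number of CTCF regions (horizontal axis) called in each exact combination of control (CT1, CT2) and TFII-I knockdown (KD1, KD2) libraries (vertical axis), from the complete lists in blue and from the 15309 strongest peaks of each list in orange. The control pair alone shares 3076 regions and the knockdown pair alone 142 with complete lists, against 894 and 811 with lists of equal length, where a region can still have a weaker call in the complete list of another library.

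The control-specific regions with the highest ranks in the control lists were peaks of well above median score. The first lay on chromosome 17 from 28300469 to 28301060, spanned 592 bp and had scores of 239 and 244 in control replicates 1 and 2, at ranks 1484 and 1163 of those lists. The nearest knockdown calls were 30064 bp away in replicate 1 and 30049 bp away in replicate 2. The region on chromosome 5 from 67054257 to 67054684 had control scores of 194 and 240.2, and the region on chromosome 15 from 101157572 to 101158032 had scores of 191 and 228. Chromosome 9 from 108756096 to 108756659 had scores of 181 and 231, and chromosome 14 from 55558102 to 55558724 had scores of 225 and 177. The region on chromosome 1 from 34659093 to 34659547 had scores of 262 and 165. On chromosome 2, the region from 25476733 to 25477255 had scores of 203 and 186, and on chromosome 7 the region from 108091637 to 108092247 had scores of 187 and 204.

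Most regions around these 8 were still called in the knockdown libraries. Within 100 kb on either side of them lay 52 other regions, 43 of which had a call in at least 1 knockdown library and 26 of which were called in all 4 libraries. Another 7 of the 52 were control-specific too. Of all 29116 regions, 40.3% were called in all 4 libraries and 10.6% were control-specific, so these counts are not read as particular to the surroundings of the 8. Around the region on chromosome 17, 8 of 9 neighbouring regions had a knockdown call and 5 were called in all 4 libraries.

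**Figure D2:**
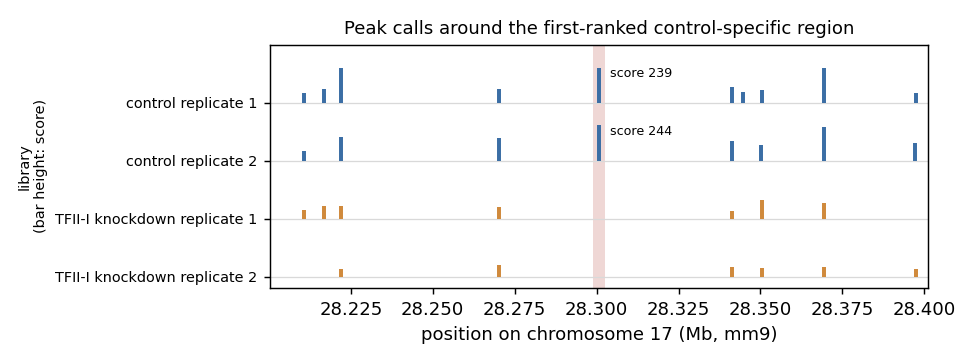
Peak calls in each of the 4 libraries (vertical axis) within 100 kb of the control-specific region on chromosome 17 from 28300469 to 28301060 (shaded), by position in Mb in mm9 (horizontal axis), with bar height proportional to the authors' score, which is printed beside the bars in the shaded region. Both control libraries have a call in the shaded region and neither knockdown library does, while 8 of the 9 neighbouring regions have a knockdown call.

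The leading knockdown-specific regions had lower scores, in lists whose scores were lower as a whole. The region on chromosome 3 from 148715344 to 148715813 scored 135 and 90.8 in knockdown replicates 1 and 2, and the nearest control calls were 296658 and 217598 bp away. On chromosome 11, the region from 97808817 to 97809053 scored 78.1 and 169, and its nearest control calls were 10222 and 10236 bp away. The region on chromosome 10 from 79371597 to 79372116 scored 107 and 89.8, and the region on chromosome Y from 2528797 to 2529242 scored 85.4 and 118. None of the 142 knockdown-specific regions reached a score of 100 in both knockdown libraries, whereas 367 of the 3076 control-specific regions did so in both controls. That cutoff is not on a common scale: 35.7% and 28.4% of all knockdown peaks reached it, against 57.1% and 55.4% of all control peaks. No difference in binding is read from these 2 counts. The 3 regions with the highest mean rank over all 4 libraries had top scores in control and knockdown alike. Chromosome 2 from 98506259 to 98507591 and chromosome 9 from 35112588 to 35113412 stood at the score ceiling of 3100 in every library. Chromosome 15 from 74915633 to 74917710 scored 3100 and 3056 in the controls and 3100 and 2461 in the knockdown libraries. These scores lie far above the median mean control score of 243 among the strongest 2078 regions called in both controls. No filter for repeat-like regions was applied, so these 3 regions are not read as strong CTCF sites that the knockdown left unchanged.

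Control-specific regions were concentrated among the weaker control peaks. Their median scores were 79.8 and 76.6 in control replicates 1 and 2, against 148 and 141 for regions called in all 4 libraries. When the 20780 regions called in both controls were divided into 10 groups of equal size by control rank, 48.3% (95% Clopper-Pearson interval 46.1 to 50.4%) of the weakest group had no call in either knockdown library. This share was 32.2% in the next group, 9.92% in group 5 and 1.11% in group 9. In the strongest group it was 0.241% (0.0782 to 0.561%), which is 5 of 2078 regions. The share called in both knockdown libraries ran from 15.7% in the weakest group to 94.5% in the strongest. In each of the 10 groups fewer regions were called in knockdown replicate 2 than in knockdown replicate 1. Weak peaks lie nearest the lowest score, so a shorter list with lower scores lacks them first. Regions called in control replicate 1 alone had a median score of 62.42, and those in control replicate 2 alone 61.15. No selective loss of weak CTCF sites is therefore read from this gradient.

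**Figure D3:**
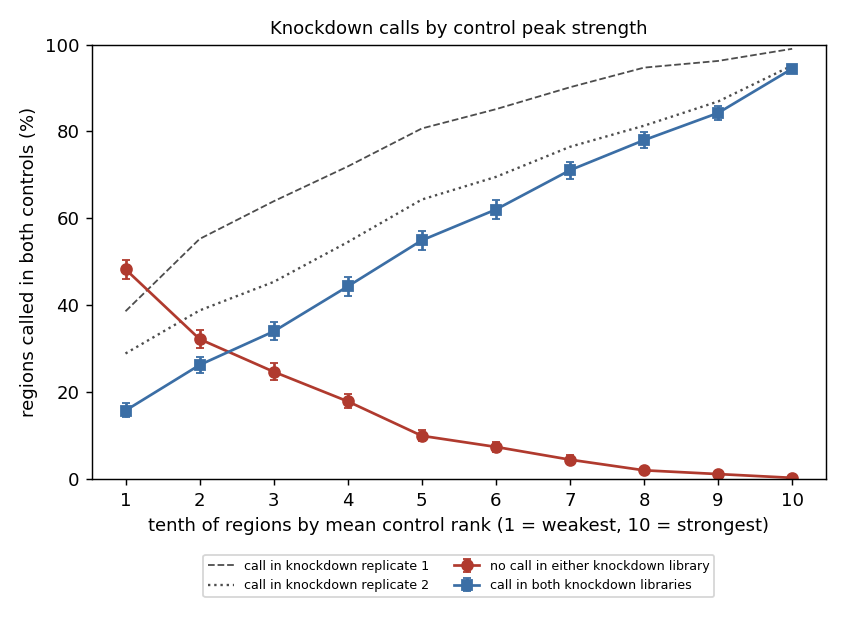
Share of the regions called in both controls, in percent (vertical axis), that had no call in either knockdown library (red), a call in both (blue) or a call in each knockdown replicate (grey lines), for 10 groups of equal size ordered by mean control rank (horizontal axis); bars are 95% Clopper-Pearson intervals. The share without a knockdown call goes from 48.3% in the weakest group to 0.241% in the strongest.

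The distribution over chromosomes was examined only after the lists had been seen. Chromosomes X and Y held more of the regions called in knockdown libraries alone than their share of all regions. On chromosome X, 110 of 871 regions (12.6%) were called in at least 1 knockdown library and in no control, and on chromosome Y 16 of 63 (25.4%), with Benjamini-Hochberg adjusted p of 4.33e-13 and 4.81e-06 by Fisher's exact test over 21 chromosomes. Over all chromosomes, 1701 of 29116 regions were called in knockdown libraries alone. The test does not match regions on strength and treats neighbouring regions as independent, and no filter for repeat-like regions was applied. Chromosome X took 6.47% of the 1701 regions called in knockdown libraries alone and 3.28% of the 7342 called in control libraries alone, an odds ratio of 2.04 (95% interval 1.60 to 2.58). It held 15 of the 142 knockdown-specific regions (10.6%, 6.03 to 16.8%) and 2.22% of the regions called in all 4 libraries, the lowest share of any class. Of the 110 regions, 61 were called in knockdown replicate 1 alone and 34 in replicate 2 alone. Chromosome X also took 3.58% and 3.80% of the regions called in control replicate 1 or 2 alone and 2.73% of the control-specific regions. Its share was 6.12% among regions called in control replicate 2 and both knockdown libraries. Control-specific regions took between 12.3% and 17.1% of the regions called in both controls on each autosome and on X, most on chromosome 11 with 278 of 1621, and none of 32 on chromosome Y, where the upper limit was 10.9%. No chromosome passed the adjusted threshold for this share (smallest adjusted p = 0.111, Fisher's exact test). That test does not account for peak strength, from which 235 control-specific regions were expected on chromosome 11.

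The order of the 11741 regions called in all 4 libraries also differed by chromosome. These regions were ranked by score within each library, and the mean control rank was subtracted from the mean knockdown rank, in percentile points. Regions on chromosome X stood 8.49 ± 1.52 points (SE over 261 regions) higher in the knockdown libraries, 9.34 points in replicate 1 and 7.65 in replicate 2, while control replicates 1 and 2 differed there by -0.453 points. This difference was uneven along chromosome X, from 0.194 ± 3.23 to 22.0 ± 3.39 points over 5 consecutive parts. Regions on chromosome Y stood 25.3 ± 3.22 points higher (SE over 31 regions), and those on chromosome 11 stood at -3.24 ± 0.753 points (889 regions). The permutation p was 1e-05 for each of these 3 chromosomes, the smallest that 100000 draws of regions can give, with an adjusted p of 7e-05. Of the 31 regions on chromosome Y, 9 were over 1 kb, and the 22 shorter ones stood 26.9 ± 3.75 points higher. No filter for repeat-like regions was applied, so a repeat-like source on chromosome Y stays open. Chromosomes 12 and 18 stood at 2.79 ± 1.04 and 3.39 ± 1.32 points, both with an adjusted permutation p of 0.0294, and the remaining chromosomes did not pass. Compared with autosomal regions of the same control rank, chromosomes 12 and 18 no longer passed, at 0.918 ± 0.855 and 1.58 ± 1.10 points (adjusted permutation p = 0.762 and 0.492). In that comparison chromosome X stood at 5.53 ± 1.28 and chromosome Y at 24.1 ± 2.82 points, both with an adjusted permutation p of 0.00021. Chromosome 11 stood at -1.82 ± 0.636 points (adjusted permutation p = 0.00609), with -0.799 ± 0.820 in knockdown replicate 1 and -2.84 ± 0.846 in replicate 2. A higher rank is relative to the other regions of the same list and gives no amount of CTCF. The tests over regions compare these 4 libraries, since neighbouring regions are not independent replicates.

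**Figure D4:**
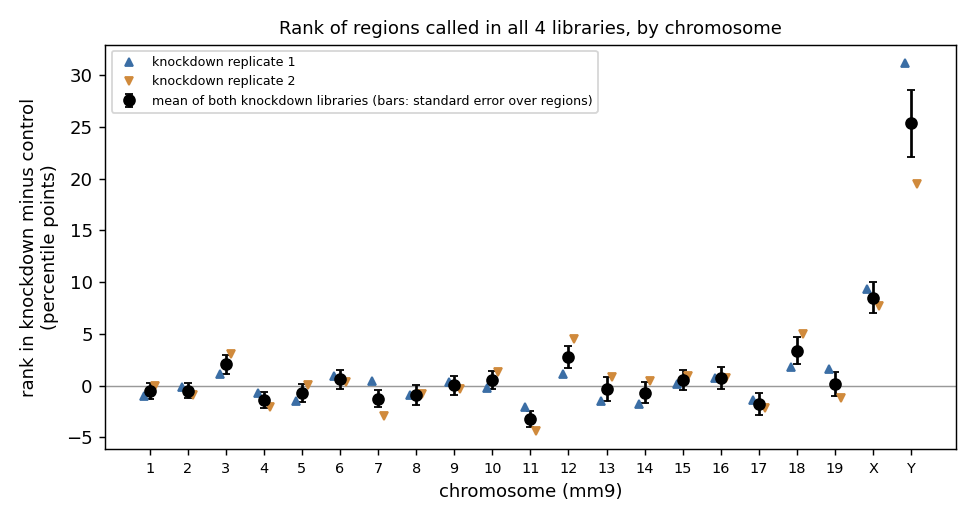
Mean rank of the regions called in all 4 libraries in the knockdown minus that in the control libraries, in percentile points (vertical axis), for each chromosome of mm9 (horizontal axis); black points are the mean of both knockdown libraries with the standard error over regions, and triangles are the single knockdown libraries. Chromosome X stands at 8.49 and chromosome Y at 25.3, above the autosomes in both knockdown libraries.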

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

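The settings without chromosomes X, Y and M, those for the rank differences of chromosomes, and the replicate block were chosen after seeing the data. Both groups kept their order in peak number with a score of at least 100, with means of 13602.5 control and 5573.5 knockdown peaks. Of the control-specific regions 367 had such a score in both controls, and of the knockdown-specific regions 0 had one in both knockdown libraries, with classes taken from the complete lists. Fewer peaks of the knockdown lists reach that score in any case (35.7% and 28.4%, against 57.1% and 55.4% in the controls). At equal list length control-specific regions numbered 894 and knockdown-specific regions 811, the share of control peaks found in the other control was 80.5%, that of control peaks in a knockdown list 74.2% and that of knockdown peaks in a control list 74.4%, while 71.7% of knockdown peaks were found in the other knockdown list. The stricter score and the equal length use fewer peaks by construction. With reciprocal overlap of 50% these shares were, in the same order, 83.8%, 55.2%, 78.4% and 64.0%, against 86.3%, 64.1%, 90.4% and 73.4% with 1 bp, and the cause was not tested. Leaving out 1 library gave 4661 (without knockdown replicate 2) to 7454 (without knockdown replicate 1) control-specific regions, and 387 (without control replicate 2) to 1103 (without knockdown replicate 2) knockdown-specific regions. By construction fewer calls are then required. Median scores averaged 144 in control and 92.1 in knockdown lists over regions called in all 4 libraries, and 141 and 87.0 at equal length, against 109 and 82.3 over complete lists, since weak peaks drop out. Reciprocal overlap, merging within 500 bp and leaving out chromosomes X, Y and M kept the control-specific count between 2992 and 3577 and the knockdown-specific count between 123 and 207. Matching on control rank ended the calls of chromosomes 12 and 18 in the rank differences and left those of chromosomes 11, X and Y. The alternatives planned for tag density, promoter shares and gene lists were not run. Depth is unknown and limits how many weak sites each list can show. With the replicate number as a block, the control lists held 5391 (replicate 1) and 8564 (replicate 2) peaks more than the knockdown lists, a mean of 6977.5 as without the block, with an exact sign-flip p of 0.5, the smallest for 2 pairs. The shared number did not go with shared deviations (Spearman correlation of 0.0129 across 11741 regions between the rank differences of the replicates in each group). The overlaps and classes have no test that a block could enter.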

Other observations

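Among the tests reported here, those of the pairings of libraries at equal list length, of a common order of site strengths, of 3 Mb windows, of differences between libraries of a group and of single knockdown libraries or chromosomes at matched control rank were chosen only after the results they measure had been seen. The permutation test between parts of chromosome X was not among the written predictions either.

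CTCF regions in densely occupied parts of the autosomes ranked lower than isolated ones in knockdown replicate 2, and at matched control rank not detectably so in replicate 1. Among regions called in all 4 libraries, those with 0 to 4 other control regions within 250 kb stood 2.92 ± 0.411 percentile points (SE over 2949 regions) higher in the knockdown than in the control libraries. Those with 14 to 50 neighbours stood at -2.81 ± 0.504 points (1885 regions), and the groups between them at 0.241, -0.854 and -2.02 points in order of density. The Spearman correlation across 11448 regions was -0.0931 (95% interval over resampled chromosomes -0.112 to -0.0752), with a negative sign on 19 of 19 autosomes. At matched control rank it was -0.0387 (-0.0534 to -0.0251), negative on 15 of 19. Taken singly at matched control rank, knockdown replicate 2 gave -0.0666 (-0.0797 to -0.0508) and knockdown replicate 1 gave 0.0127 (-0.00439 to 0.0286). Control-specific regions were 0.968 times as frequent as their strength predicts in the sparsest group and 1.09 times in the densest.

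Gathering of control-specific regions in single parts of the genome did not pass the test of the highest window. The highest excess among 698 windows of 3 Mb was a z of 4.13, on chromosome 17 from 84000001 to 87000000, where 12 of 23 regions were control-specific and 4.57 were expected from their strength. The 95th percentile of the highest z over 1000 shuffles was 4.47 (permutation p = 0.109). With a z over 3 there were 5 windows, against a median of 2 in the shuffles, 73 of 1000 of which had 5 or more. Chromosome 11 as a whole held 278 control-specific regions where 235 were expected from strength, a z of 3.35 among 21 chromosomes.

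For the first pattern weighed, the shorter knockdown lists, the score steps gave a background of 1.91 ± 0.0368 tags per window (SD, n = 2) in control and 1.25 ± 0.0450 in knockdown libraries, 65.6% of the control level. Lower depth may account for part of the difference, but tags per window also depend on the width of the window, which is not given. The estimate rests on the 239 to 549 peaks per list that lay on the steps, and the thinning takes its ratio as one of depth. Control lists thinned to that level kept 20524.8 peaks on average, 20019 with a local background 2 times as high and 19568 (18631 to 20382) at 4 times, against 19076 and 15309 observed, and all 12 thinned lists were longer than the knockdown list they were thinned to. This leaves depth open all the same, as the local background is assumed and the thinned peaks keep the chance excess that got them called: 3614 of the 24467 peaks of control replicate 1 had no call in control replicate 2. At equal list length 1705 regions were still specific to the control or knockdown pair, against 1189 and 1104 for the other pairings. Unequal length is therefore not the whole source of the larger count of the group pairing. Equal length does not equalise noise, however: 80.5% of peaks were then shared within the control pair and 71.7% within the knockdown pair. Noisier knockdown lists around one common order of sites could also give the group pairing the larger count, which was not tested on these counts. The product of the rank correlations within groups was 1.17 times (1.11 to 1.24) that between groups, where 20 simulations of one common order gave 0.925 to 1.04. The control pair correlated at 0.602 and the knockdown pair at 0.367, which lay below all between-group pairs (0.393 to 0.474). A ratio of products does not show which of the pairs carries the excess. The simulations also assume a distribution of site strengths. The knockdown, the precipitation and any batch or input shared within a group cannot be told apart.

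The second pattern is the higher rank of chromosome X regions in the knockdown libraries. Without regions over 1 kb the difference was 7.84 ± 1.58 points (243 regions), which argues against regions of that width as its whole source. Repeat-like signal in shorter regions was not tested. For example, the region on chromosome 9 at the score ceiling in every library spanned 825 bp. Over autosomal regions of the same control rank it was 5.53 ± 1.28 points, so movement of weak regions in noisier lists could account for part of the 8.49 points and not for all of it. For a change along the whole chromosome, such as a different copy number of X in the knockdown line, 5 consecutive parts with about equal numbers of regions were compared. In order they stood at 9.44 ± 3.55, 22.0 ± 3.39, 4.19 ± 3.33, 6.67 ± 2.77 and 0.194 ± 3.23 points, so 5 of 5 means were above 0. The parts differed from each other (permutation p = 0.0001, the smallest that 10000 permutations can give), and the highest ran from position 9.93e+07 to 1.31e+08. The prediction written for such a change was only that 5 of 5 means lie above 0. The parts were not matched on control rank, and neighbouring regions are not independent. Their unevenness therefore does not decide the question, and a change along the whole chromosome stays open. Base composition and an effect of TFII-I itself were not tested.

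The third pattern is the lower rank of densely surrounded regions. The correlation left at matched control rank was -0.0387 for the mean of both knockdown libraries. In knockdown replicate 2 it was -0.0666 (-0.0797 to -0.0508), which argues against strong regions falling back in noisier lists as the whole source there. In knockdown replicate 1 it went from -0.0340 (-0.0548 to -0.0150) without matching to 0.0127 (-0.00439 to 0.0286) with it, so that source stays open there. The knockdown libraries differed from each other as much: the difference of knockdown replicate 1 minus replicate 2 correlated with density at 0.0593 (0.0428 to 0.0752) at matched control rank, and that of control replicate 1 minus replicate 2 at 0.0194 (0.00643 to 0.0360). The relation is thus in line with a difference between single libraries, and no group difference can be read from it. The GC content favoured by each library preparation remains a candidate explanation that was not tested, as the mm9 sequence was not used here.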
